A study of Mus musculus with 8 samples.

How the data were processed

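Gene expression was measured by RNA sequencing in 8 libraries from mouse cells. Per the labels' protocols, total RNA was depleted of ribosomal RNA, made into strand-specific libraries and sequenced as paired reads of 100.0 bases. The authors deposited one table of FPKM (fragments per kilobase of transcript, scaled to the fragments sequenced) with a column per library, and the submitters' processing notes name TopHat2 2.0.8, Cufflinks 2.0.2 and the mouse genome build mm9. The annotation, the scaling between libraries and the strand setting are not given in the sources used here, so genes that overlap, lie antisense to each other or have near-identical copies are uncertain. Each column was matched to its library by its name. The mm10 reference genome was not used, and coordinates are those of the deposited table in mm9, with starts moved to count from 1 because 883 of 978 olfactory receptor loci (90.3%) then had lengths that are multiples of 3.

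The table held 23699 entries for 23235 gene symbols. Entries sharing a symbol (712 entries of 248 symbols) were summed. Genes with an FPKM of at least 1 in at least 1 of the 8 libraries were tested, 12642 in all. A list member low in most groups was tested only if some library reached 1 FPKM, which raises the share of tested members that differ. The number of reads is unknown, so no counting error was computed and the precision rests on the spread between libraries. Some zeros in the table are not absence of expression. Hmgcs1 was listed at 0 in all 8 libraries, Ppia stayed below 1.2 FPKM, Gapdh lay between 0.996 and 2.31, and 36 of 82 ribosomal protein genes stayed below 10 FPKM in every library. Such genes are given as listed, library by library.

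From these FPKM values, log2(FPKM + 1) was tested with limma 3.58.1 in R 4.3.3, in a model with 1 mean per group over all 8 libraries and a variance trend, two-sided, with Benjamini-Hochberg adjustment over all tested genes at 0.05 and no fold minimum. The 3 induced replicates with MBP and the 2 uninduced replicates gave the 3 residual degrees of freedom, to which limma's prior added 3.24. The groups with 1 library each were assumed to vary like the replicated groups. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The 5 comparisons were induced cells with MBP against uninduced cells, fibroblasts, OPCs and induced cells without MBP, and uninduced cells against fibroblasts.

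A set of 25 gene lists for cell types and pathways was fixed before the data were examined. Each was tested with camera at a preset correlation of 0.01 and again with an estimated correlation, with adjustment over the 25 lists of a comparison, and its members were also adjusted over the list alone. With an estimated correlation none of the 68 list calls of the 5 comparisons held. The estimate was 0.73 for the cell cycle list, 0.87 for p53, 0.88 for interferon and 0.94 for macrophages. For such lists the preset of 0.01 is far too low, and small p-values at the preset overstate the evidence. It was -0.17 for the melanocyte list and -0.008 for the immediate early list, whose calls were lost too, so correlation alone does not account for every loss. A library's position between fibroblast and OPC was its log2 value minus that of fibroblasts, divided by the difference between OPCs and fibroblasts, over genes at least 8-fold apart, without a test. Genes were named by a rule fixed before the data were examined. It took, in the comparison of induced and uninduced cells, the lineage factors, the 10 largest rises and 10 largest falls among called genes whose groups did not overlap, leaving out small RNA and unnamed genes, and up to 4 members of each list by size of change, passing ones first. In the other comparisons it took 5 and 5 genes and up to 2 members per list. Of the 331 gene results it took over the 5 comparisons, 165 are named, and the rest enter the counts of their lists only or are not reported here. In addition, 40 of the 205 named results were chosen after their values were seen.

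The tests were tried on simulated data, 10 simulations per comparison over 12642 genes. A lone library has no spread of its own, so the simulations could not test whether groups with 1 library vary like the replicated groups. Each simulation held a fixed number of changed genes, far fewer than the 3605 called in the data for induced against uninduced cells. The 193.6 genes that a simulation of that comparison called on average follow from this setting. They are neither a count expected by chance nor a reference for the data. The simulated noise was also independent between genes, unlike that of real genes that vary together. The recovered shares and false calls that follow describe the simulated data only. In the comparison of induced and uninduced cells 80.5% of simulated 2-fold changes and 99.8% of 4-fold changes were recovered, with 6.85% false calls. The share of 2-fold changes recovered was 47.1% against fibroblasts, 48.9% against OPCs, 44.9% against induced cells without MBP and 37.7% for uninduced cells against fibroblasts, with 98% or more of 4-fold changes and false calls of 6.21% to 7.56%. Alternatives were another pseudocount, other filters, median-of-ratios scaling, quantile normalization, leaving out small RNA genes, 1 entry per symbol, no variance trend, a fold minimum, a replicate block, only the 5 replicated libraries and each replicate left out in turn. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.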

Results

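Gene expression was measured in mouse cells taken between fibroblast and oligodendrocyte precursor cell (OPC), the glial cell that divides and gives rise to myelin-forming oligodendrocytes. The fibroblasts were embryonic fibroblasts from shiverer mice, which carry a deletion in Mbp, the gene of myelin basic protein, and had been depleted with beads against A2B5, a surface marker of glial precursors. They were infected with reprogramming factors under doxycycline control to make induced OPCs, and the series title names replacement of the missing gene as a second aim. The 8 libraries fell into 5 groups. These were 3 replicates of induced cells given an MBP transgene, 1 library of induced cells without it, 2 replicates of infected cells that were never induced, 1 library of the starting fibroblasts and 1 library of OPCs made from epiblast stem cells, a pluripotent cell of the early embryo. The induced and uninduced cells were collected on day 21.

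Total RNA without ribosomal RNA was sequenced, and each gene's value was FPKM (fragments per kilobase of transcript, scaled to the fragments sequenced). Total FPKM ranged from 155909 in the induced library without MBP to 226981 in induced replicate 1, and between 10283 genes (OPC) and 11128 genes (induced replicate 3) reached 1 FPKM. The number of reads behind a value is unknown, because FPKM carries no depth. Small nuclear, nucleolar and other small RNA genes took 9.38% of the FPKM in the OPC library and 11.95% to 18.6% in the 3 induced replicates with MBP. Rank correlations across the 12642 tested genes, which are not independent replicates, were 0.968 to 0.985 among the 3 induced replicates and 0.973 between the 2 uninduced ones. The OPC library correlated at 0.669 to 0.672 with the induced replicates, at 0.691 with the induced library without MBP, at 0.602 and 0.578 with the uninduced libraries and at 0.647 with fibroblasts. Correlations with the fibroblast library were higher, 0.848 to 0.872 for the induced replicates, 0.845 without MBP, and 0.906 and 0.898 for the uninduced libraries. Values below are mean ± SD over the 3 induced libraries with MBP or over the 2 uninduced libraries, single values elsewhere, and fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes.

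The deleted gene and the lineage factors come first. Mbp (chromosome 18, 82644515 to 82755029, mm9) was at 0.672 ± 0.201 FPKM in induced cells with the transgene, 0.368 without it, 0.455 ± 0.166 in uninduced cells, 0.223 in fibroblasts and 0.318 in OPCs. The difference with against without the transgene was 0.28 on the log2 scale with a 95% interval of -0.19 to 0.75. This value checks neither the genotype nor the transgene, because the shiverer deletion removes only part of the gene and the labels do not say which sequence the transgene carries. The labels also do not name the delivered factors. Transcription factors of the oligodendrocyte lineage listed beforehand were Olig2, which specifies OPCs, Sox10, which drives myelin genes, Nkx6-2 and Zfp536. Sox10 (chromosome 15, 78985343 to 78994920) was at 92.6 ± 5.48 FPKM in induced cells, 84.6 in induced cells without MBP, 2.6 ± 0.998 in uninduced cells, 10.4 in OPCs and 0 in fibroblasts. Olig2 (chromosome 16, 91225795 to 91228922) was at 47.1 ± 14, 44, 1.14 ± 0.735, 127 and 0.0416 FPKM in the same order, and Nkx6-2 (chromosome 7, 146765275 to 146768696) at 41 ± 12.3, 27.1, 3.92 ± 2.45, 1.12 and 0.0941. Zfp536 (chromosome 7, 38264128 to 38554771) was at 7.38, 9.58 and 7.27 FPKM in the induced replicates, 7.52 without MBP, 0 and 0.459 in the uninduced replicates, 0.196 in OPCs and 0.0699 in fibroblasts. Native and delivered transcripts cannot be separated in these values.

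What doxycycline induction changed was asked by comparing the 3 induced libraries with MBP with the 2 uninduced ones. This comparison cannot separate the factors from doxycycline itself, nor from the MBP transgene if the uninduced cells lacked it. Gpr17, a receptor of OPCs about to differentiate, reached 56.4 ± 4.19 FPKM against 0.0606 ± 0.0654 (chromosome 18, 32102653 to 32109290; a rise of 5.76, SE 0.13, limma adjusted p = 1.7e-05). Pmel, a structural protein of pigment granules, reached 100.4 ± 3.94 against 0.268 ± 0.0692 (chromosome 10, 128143314 to 128157294; 6.32, SE 0.12, limma adjusted p = 1.7e-05). In the other direction Igf2, a fetal growth factor, fell from 291 ± 80.1 to 49 ± 13.6 FPKM (fell by 2.56, SE 0.29, limma adjusted p = 0.00236). Dpt, a dermal matrix protein, fell from 15 ± 0.328 to 3.57 ± 0.36 (fell by 1.81, SE 0.13, limma adjusted p = 5.5e-04). Other large rises were those of Cytl1, at 127, 68.5 and 96.5 FPKM in the induced libraries and listed at 0 in both uninduced ones, and of Serpina3n, a protease inhibitor of the acute phase that reached 1071 ± 253 against 17 ± 4.85. With them rose Col20a1, Synpr, a synaptic vesicle protein, Moxd1, Hapln1, which links hyaluronan to proteoglycans, and Col9a1, a cartilage collagen. The other largest falls were those of Efemp1, a matrix glycoprotein (109 ± 15.3 to 13.6 ± 10.2), and of Slfn5 (22.8 ± 8.39 to 2.14 ± 0.772). With them fell the surface antigen gene Ly6c1, the chemokine gene Ccl20, Iigp1, an interferon-induced GTPase, Pappa2, Ptx3, a soluble pattern receptor, and Ces2e, an esterase.

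limma called 3605 of 12642 genes, 2721 higher and 884 lower in induced cells, of which 843 and 384 changed at least 2-fold. The median change of all genes was 0.18, and scaling by the median ratio moved the split from 75.5% higher to 50.8% (2072 higher, 2003 lower), quantile normalization to 50.1% and leaving out small RNA genes to 62.1%. The count was 1400 without uninduced replicate 2, 1601 without induced replicate 3 and 2212 without uninduced replicate 1. Of the 93 named genes past the threshold, 44 lost their call in at least 1 such omission, among them Efemp1 (without uninduced replicate 2), Ly6c1, Ccl20 and Iigp1.

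**Figure D1:**
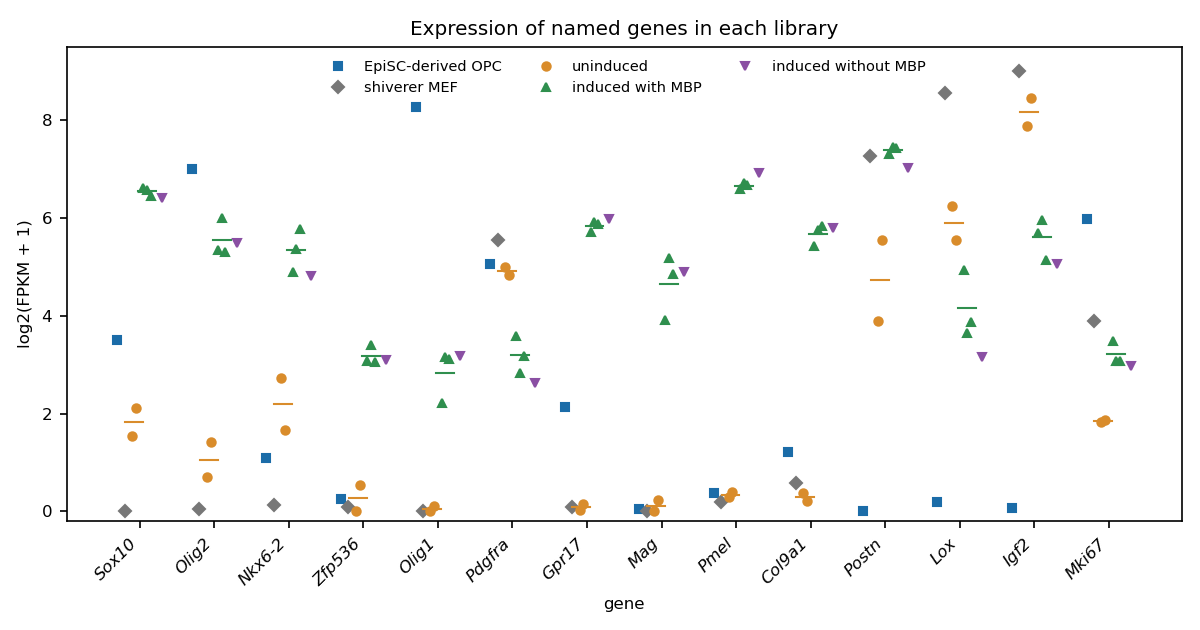
Expression on the log2(FPKM + 1) axis of 14 genes in each of the 8 libraries, 1 symbol per library, with short lines at the means of the 3 induced libraries with MBP and the 2 uninduced libraries. Pmel lies near 100 FPKM in the 4 induced libraries and below 1 FPKM elsewhere, while Olig1 is at 308 FPKM in the OPC library and at 3.66, 7.89 and 7.71 in the induced libraries with MBP.

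More oligodendrocyte lineage genes rose than fell. All 4 lineage factors rose (4 adjusted over the list alone; camera adjusted p = 4.2e-04, adjusted p = 0.356 with an estimated correlation), Sox10 by 4.73 (SE 0.19) and Olig2 by 4.50 (SE 0.30). Native and delivered transcripts of these 4 cannot be separated, so their rise does not show a change in native expression. Of 28 tested OPC genes, 17 rose and 2 fell (18 and 2 adjusted over the list alone; camera adjusted p = 8.4e-05, adjusted p = 0.356 with an estimated correlation). Sox6, a factor that holds OPCs in the precursor state, reached 24.2 ± 1.83 FPKM against 0.697 ± 0.111, and Luzp2 reached 31 ± 8.06 against 0.172 ± 0.0307. The 2 that fell were chosen after their values were seen. Pdgfra, the growth factor receptor that marks OPCs and is also made by fibroblasts, fell from 29.2 ± 2.29 to 8.41 ± 2.51 FPKM (fell by 1.71, SE 0.23, limma adjusted p = 0.00431), and Pcdh15, a cadherin, was below 1 FPKM in both groups. The list of myelinating oligodendrocytes held 36 genes, of which 35 were measured and 24 reached 1 FPKM in a library and were tested. Of these 24, 14 rose and none fell (16 adjusted over the list alone; camera adjusted p = 5.5e-05, adjusted p = 0.356 with an estimated correlation; 13 rose and 1 fell after median-ratio scaling). Ugt8a, an enzyme of galactolipid synthesis, reached 34.2 ± 0.869 FPKM against 0.0615 ± 0.0244. Cnp, an enzyme of uncompacted myelin, reached 75.5 ± 6.79 against 6.03 ± 0.0215, and Mag, an adhesion protein of the myelin sheath, was at 14.2, 35.2 and 27.8 FPKM in the induced libraries and at 0 and 0.168 in the uninduced ones. The call of Pcdh15 was lost without induced replicate 3 or without uninduced replicate 2.

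Genes of peripheral glia and some genes of pigment cells, 2 derivatives of the neural crest, rose with them. The pigment genes Tyr, Tyrp1, Mlana, Slc45a2 and Trpm1 had means of at most 0.437% of that of Pmel over the 3 induced libraries. Of 18 tested Schwann cell genes, 14 rose and none fell (14 adjusted over the list alone; camera adjusted p = 9.3e-07, adjusted p = 0.356 with an estimated correlation). Erbb3, the neuregulin receptor of Schwann cells, reached 32.1 ± 2.94 FPKM against 0.348 ± 0.44. The Schwann list shares, among others, Sox2 and Fabp7 with the neural progenitor list, Gap43 with the neuron list and Egr2 with the immediate early list. The melanocyte list held 11 genes, of which 10 were measured and 6 reached 1 FPKM in a library and were tested. Of these 6, 4 rose (4 adjusted over the list alone; camera adjusted p = 0.00596, adjusted p = 0.356 with an estimated correlation). These were Pmel, Dct, an enzyme of melanin synthesis listed at 0 in the uninduced libraries and at 2.87, 2.99 and 2.74 FPKM in the induced ones, Ednrb and Mitf. The endothelin receptor gene Ednrb was at 12.3 ± 2.87 against 1.41 ± 0.176, and Mitf, the main regulator of pigment cells, at 7.63 ± 0.292 against 4.08 ± 0.833. The call of Mitf was lost without induced replicate 3 or without uninduced replicate 2.

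More fibroblast genes fell than rose. Of 32 tested, 13 fell and 2 rose (15 and 2 adjusted over the list alone; camera adjusted p = 9.2e-09, adjusted p = 0.356 with an estimated correlation; 19 fell after median-ratio scaling). Lox, which crosslinks collagen, fell from 60.7 ± 20.9 to 18.2 ± 9.81 FPKM along with Dpt. The 2 that rose were Postn, a secreted matrix protein, from 29.9 ± 22.5 to 168 ± 8.18 FPKM, and Fn1, fibronectin, from 119 ± 32.9 to 285 ± 32.6, the latter chosen after its values were seen. Of 11 tested contractile smooth muscle genes, 4 fell and 2 rose (6 and 3 adjusted over the list alone; camera adjusted p = 0.0373, adjusted p = 0.585 with an estimated correlation). That list call was lost after median-ratio scaling (camera adjusted p = 0.183), without induced replicate 3 (0.0557) and without uninduced replicate 1 (0.0508). Tagln and Tpm2, which bind actin filaments, fell from 59.2 ± 7.28 and 20.3 ± 6.52 FPKM to 18.2 ± 10.6 and 6.99 ± 3.45. Actg2, a smooth muscle actin, fell from 2.08 ± 0.536 to 0.552, and Lmod1 fell from 0.788 ± 0.0435 to 0.284 ± 0.054, while the myosin genes Myh11 and Myl9 rose to 3.78 ± 0.397 and 45.1 ± 10.8 from 0.225 ± 0.048 and 19.5 ± 2.46. Actg2 and Lmod1 were chosen after their values were seen. Calls were lost without at least 1 library for Lox, Fn1, Tagln, Tpm2, Lmod1 and Myl9, those of Fn1 and Myl9 without uninduced replicate 2 alone.

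In the interferon, p53 and fat cell lists some genes fell and none rose. Of 22 tested interferon response genes, 9 fell (13 adjusted over the list alone; camera adjusted p = 2.3e-10, adjusted p = 0.417 with an estimated correlation). Ifi44, induced by interferon, was at 16.6 and 45.3 FPKM in the uninduced libraries and at 5.29, 2.76 and 4.51 in the induced ones, and Oasl2, an antiviral protein, at 5.9 and 19.6 against 2.3, 1.38 and 1.68. The median over this list was 6.89 FPKM in uninduced replicate 1 and 19.7 in replicate 2. Of 16 tested p53 and senescence genes, 7 fell (8 adjusted over the list alone, 13 after median-ratio scaling; camera adjusted p = 3.5e-07, adjusted p = 0.417 with an estimated correlation). Mdm2, the ubiquitin ligase that degrades p53, fell from 138 ± 29.9 to 64.4 ± 20.8 FPKM, and Perp, a p53 target, from 129.9 ± 30.9 to 36.5 ± 19. Of 8 tested adipocyte genes, 6 fell (7 adjusted over the list alone; camera adjusted p = 3.5e-07, adjusted p = 0.356 with an estimated correlation), led by Fabp4, a fatty acid carrier, from 72.7 ± 34 to 17.4 ± 4.39 FPKM. Calls were lost for Oasl2 without induced replicate 3, and for Mdm2 and Perp without that library or without either uninduced replicate, Mdm2 also without induced replicate 2.

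Most cell cycle genes rose. Of 28 tested, 20 rose and none fell (22 adjusted over the list alone; camera adjusted p = 1.0e-05, adjusted p = 0.543 with an estimated correlation). Top2a, which untangles DNA before division, rose from 5.31 ± 0.357 to 16.2 ± 2.25 FPKM, and Mki67, a marker of dividing cells, from 2.61 ± 0.0682 to 8.35 ± 1.58. Of 29 tested Hox genes, which mark position along the body axis, 4 fell and 1 rose (2 and 0 adjusted over the list alone, and 8 fell and 0 rose after median-ratio scaling; camera adjusted p = 5.5e-04, adjusted p = 0.356 with an estimated correlation). Hoxb6 fell from 2.53 ± 0.668 to 0.456 ± 0.0608 FPKM and Hoxb2 from 2.98 ± 0.387 to 1.17 ± 0.187, and Hoxc10 and Hoxb3 fell by 0.51 and 0.44, while Hoxa6 rose by 0.58 and lost its call under median-ratio scaling. Hoxb3 was chosen after its values were seen. The calls of Hoxc10, Hoxb3 and Hoxa6 were each lost in at least 4 of the 5 omissions.

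The other neural lists went both ways and were not called by camera. Of 16 tested astrocyte genes, 8 rose and 3 fell (9 and 5 adjusted over the list alone, 7 and 6 after median-ratio scaling; camera adjusted p = 0.587). S100b, a calcium-binding protein also made by Schwann cells and oligodendrocytes, rose from 1.53 ± 0.222 to 55.2 ± 11.3 FPKM and Aldoc, an aldolase, from 0.784 ± 0.111 to 9.17 ± 1.61. Aldh1l1, a folate enzyme, Sox9, a glial and cartilage factor, and Glul, glutamine synthetase, fell by 0.85, 0.90 and 0.80 and were chosen after their values were seen. Of 13 tested neuron genes, the neurofilament genes Nefl and Nefm rose to 9.44 ± 3.16 and 3.2 ± 0.692 FPKM from 1.3 ± 0.503 and 0.887 ± 0.0581. The neuronal genes Stmn2 and Snap25 fell to 2.47 ± 2.21 and 0.357 ± 0.255 from 9.7 ± 4.09 and 1.08 ± 0.295 (2 and 2 adjusted over the list alone; camera adjusted p = 0.416). Of 12 tested neural progenitor genes, Sox2, Nes and Fabp7 rose to 7.32 ± 3.58, 17.6 ± 6.14 and 21.9 ± 5.3 FPKM from 0.176 ± 0.126, 7.58 ± 2.5 and 0.702 ± 0.562. Egfr, the receptor of epidermal growth factor, fell to 6.16 ± 1.81 from 20.8 ± 0.681 (3 and 1 adjusted over the list alone; camera adjusted p = 0.853). The only tested pluripotency gene, Lin28b, was listed at 0 in the uninduced libraries and at 0.0148, 0 and 0.0628 FPKM in the induced ones and did not pass. Calls were lost without at least 1 library for Aldh1l1, Sox9, Glul, Stmn2, Snap25 and Nes.

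Markers of cells that such cultures could also hold were measured. Of 16 tested macrophage genes only Cd14, a co-receptor for bacterial lipid, rose, from 5.34 ± 0.504 to 22.1 ± 9.02 FPKM (1 adjusted over the list alone; camera adjusted p = 0.365). Camera's direction for this list rested on single libraries, up without induced replicate 1 (adjusted p = 0.00582), down without induced replicate 2 (0.0459) and down without uninduced replicate 1 (0.040). The list median was 0.941 FPKM in induced replicate 1 against 6.98 and 9.42 in the other replicates. Of 4 tested endothelial genes Tek, a receptor of angiopoietins, fell from 0.329 and 0.272 FPKM in the uninduced libraries to 0.0169, 0 and 0.0533 in the induced ones. Emcn fell by 1.06 and Egfl7 rose by 0.80 (2 and 1 adjusted over the list alone; camera adjusted p = 0.216). Egfl7 lost its call after median-ratio scaling. Of 4 tested epithelial genes Wt1 rose by 1.20, Epcam rose from 0.0872 and 0 FPKM to 0.627, 1.66 and 1.1, and Krt19, a keratin, fell by 1.66 (2 and 1 adjusted over the list alone; camera adjusted p = 0.853). Of 2 tested skeletal muscle genes Des, the filament protein desmin, fell by 0.43 (1 adjusted over the list alone; camera adjusted p = 0.0507), and the list was called downward without induced replicate 2 (camera adjusted p = 0.0459) or without uninduced replicate 1 (0.0282). Of 10 tested cartilage and bone genes, 5 rose and Sox9 fell (5 and 2 adjusted over the list alone; camera adjusted p = 0.173). These 5 were the cartilage matrix genes Acan, at 5.02, 8.08 and 8.51 FPKM against 0.0727 and 0, Col2a1, Col9a1, Col11a1 and Matn1. The collagen genes rose from 1.09 ± 0.361, 0.222 ± 0.0972 and 7.2 ± 0.522 to 49 ± 11.9, 50.4 ± 7.53 and 209 ± 6.06 in that order. Matn1 was listed at 0 in both uninduced libraries and at 2.12, 5.53 and 8.28 in the induced ones and chosen after its values were seen. Calls were lost without at least 1 library for Cd14, Tek, Emcn, Egfl7, Epcam, Krt19, Des and Matn1.

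The remaining pathway lists were not called on the deposited values of all libraries. Of 15 tested targets of TGF-beta and YAP, Skil and Tgfb2 rose by 0.97 and 1.04, and 3 fell, among them Ltbp2 and Thbs1, which fell by 1.46 and 1.55 (3 and 4 adjusted over the list alone; camera adjusted p = 0.173). Of 13 tested immediate early genes, Fos rose by 1.34 and Fosl1, Junb and Dusp1 fell by 1.42, 0.69 and 0.70 (2 and 3 adjusted over the list alone; camera adjusted p = 0.0964). That list was called downward without induced replicate 2 (camera adjusted p = 0.0363) and without uninduced replicate 1 (0.0219). Of 22 tested cholesterol synthesis genes, Dhcr7, Ebp and Acat2 rose by 0.51, 0.40 and 0.54 (0 adjusted over the list alone; camera adjusted p = 0.0889), but after median-ratio scaling 0 rose and 9 fell. The list was called downward after that scaling (camera adjusted p = 0.0139) and without uninduced replicate 2 (0.0434). Of 15 tested housekeeping genes, Gusb rose by 0.74 and B2m, a subunit of class I antigen presentation, fell by 0.95 (0 adjusted over the list alone; camera adjusted p = 0.329). The calls of Tgfb2, Fos, Dhcr7, Ebp, Acat2 and Gusb were lost after median-ratio scaling, and of the genes in this paragraph only Skil kept its call in all 5 omissions. For the lists of TGF-beta targets, neurons, neural progenitors, macrophages, pluripotency and housekeeping genes the median change was positive while camera pointed down, because camera compares a list with all other genes, whose median was 0.18, and the mean change of the TGF-beta list was -0.06.

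**Figure D2:**
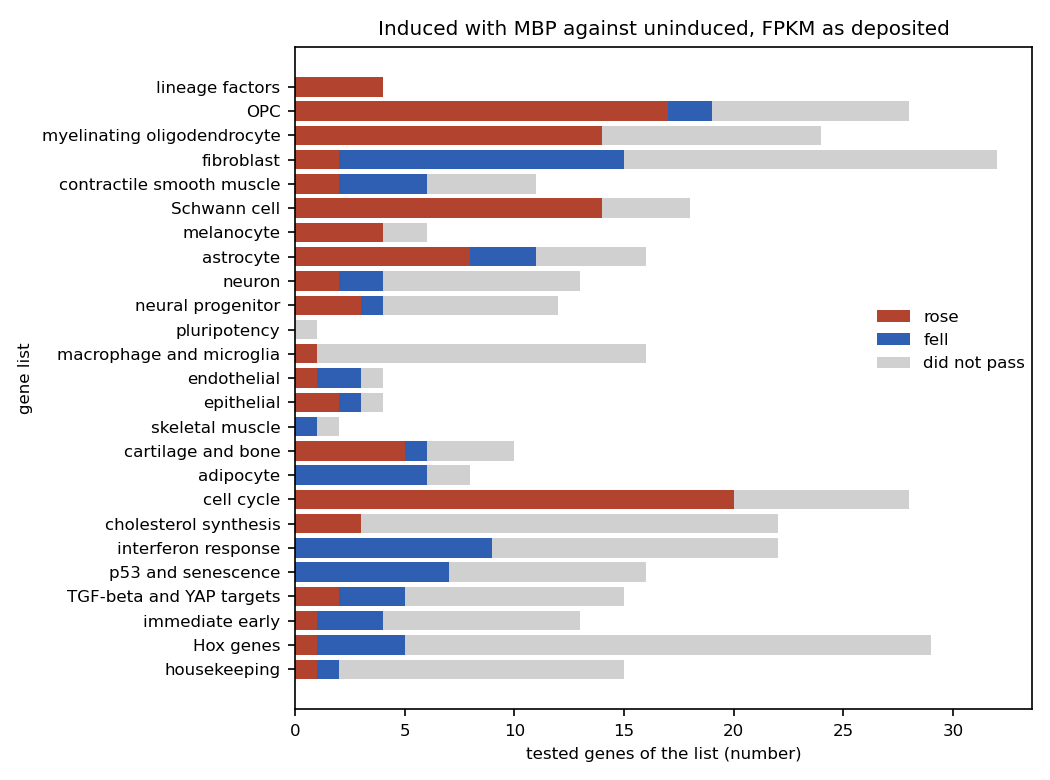
Number of tested genes of each of the 25 lists (horizontal axis) that rose, fell or did not pass limma's threshold in the 3 induced libraries with MBP against the 2 uninduced libraries, on FPKM as deposited. All 4 lineage factors rose, with native and delivered transcripts not separated, and so did 14 of 18 Schwann cell genes. Of 22 interferon response genes 9 fell, whereas the 3 cholesterol synthesis genes that rose did not pass upward after median-ratio scaling.

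How far induced cells had left the starting fibroblasts was asked by comparing them with the single fibroblast library. Col1a1, the main fibroblast collagen, was at 33 ± 7.31 FPKM against 523 in fibroblasts (fell by 3.96, SE 0.24, limma adjusted p = 3.5e-04). Ogn, a small matrix proteoglycan, was at 4.11 ± 0.200 against 223, and Rspo2, a Wnt agonist, at 0.665 ± 0.272 against 48.1, with C1qtnf3, Ptx3 and Aspn, a further matrix proteoglycan, completing the 5 largest falls. Among the largest rises were Serpina3n, from 2.75 to 1071 ± 253 FPKM, Lcn2, an iron-scavenging protein of the acute phase listed at 0 in fibroblasts and at 284, 108 and 205 in the induced libraries, Sox10, Col20a1 and Pmel. Lcn2 was also at 142 and 107 FPKM in the uninduced libraries, and Col1a1 was at 55.3 ± 1.39 FPKM there. The median over the fibroblast list was 73.3 FPKM in fibroblasts and 29.2 and 46.0 in the uninduced libraries. It was 27.7, 26.0 and 26.8 in the induced libraries with MBP. Part of the distance from fibroblasts was therefore present without induction.

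By list, all 4 lineage factors were higher than in fibroblasts (4 adjusted over the list alone; camera adjusted p = 3.1e-05, adjusted p = 0.171 with an estimated correlation), Olig2 by 5.49, Nkx6-2 by 5.22 and Zfp536 by 3.08. Of 28 OPC genes 16 were higher, among them Gpr17 by 5.76, and Pdgfra was lower with a change of -2.36 (18 and 1 adjusted over the list alone; camera adjusted p = 3.5e-08, adjusted p = 0.217 with an estimated correlation). Of 24 myelin genes 13 were higher (15 higher and 1 lower adjusted over the list alone; camera adjusted p = 3.5e-08, adjusted p = 0.217 with an estimated correlation). Of 18 Schwann cell genes 13 were higher (15 higher and 1 lower adjusted over the list alone; camera adjusted p = 2.2e-07, adjusted p = 0.217 with an estimated correlation). S100b, of the astrocyte list, was higher by 5.03. Of 32 fibroblast genes 20 were lower and 12 did not pass, with Lox at 18.2 ± 9.81 against 374 FPKM (22 lower and 1 higher adjusted over the list alone; camera adjusted p = 9.6e-13, adjusted p = 0.171 with an estimated correlation). Of 11 contractile genes 8 were lower, led by Actg2 and Tagln, and Myh11 and Rgs5 were higher (8 and 2 adjusted over the list alone; camera adjusted p = 7.0e-05, adjusted p = 0.346 with an estimated correlation). Of 28 cell cycle genes 6 were lower, among them Ccnb2, a mitotic cyclin, and Kif20a, a spindle motor (10 adjusted over the list alone, 16 after median-ratio scaling). Of 22 cholesterol synthesis genes 9 were lower, among them Cyp51 and Fdft1, enzymes of sterol synthesis (12 adjusted over the list alone, 16 after median-ratio scaling). Camera gave adjusted p = 3.5e-08 for both, which became adjusted p = 0.410 with an estimated correlation for the cell cycle and adjusted p = 0.323 with an estimated correlation for cholesterol synthesis. Of 15 TGF-beta and YAP targets Thbs1, Ltbp2, Tgfb3 and Bgn were lower (9 adjusted over the list alone; camera adjusted p = 1.4e-04, adjusted p = 0.283 with an estimated correlation), and no interferon response gene passed in this comparison. Camera called 4 further lists. Melanocyte genes were called upward (median change 1.53; camera adjusted p = 1.7e-04, adjusted p = 0.171 with an estimated correlation) and skeletal muscle genes downward (median change -1.74; camera adjusted p = 4.4e-04, adjusted p = 0.217 with an estimated correlation). Of 13 immediate early genes 6 were lower (6 adjusted over the list alone, 5 after median-ratio scaling; camera adjusted p = 3.6e-05, adjusted p = 0.171 with an estimated correlation), and so were 6 of 29 Hox genes (6 adjusted over the list alone; camera adjusted p = 3.6e-05, adjusted p = 0.217 with an estimated correlation). Nkx6-2, Zfp536, Pdgfra, Myh11, Rgs5, Tgfb3 and Bgn were chosen after their values were seen. For the lineage factors, native and delivered transcripts cannot be separated in this comparison either.

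limma called 2310 genes, 1522 higher and 788 lower, 65.9% higher as deposited, 54.1% after median-ratio scaling and 48.9% after quantile normalization. The count was 1331 without induced replicate 3, and 5 of the 30 named genes (Bgn, Ccnb2, Fdft1, Kif20a and Rgs5) lost their call in at least 1 omission. With a single fibroblast library, its spread was taken from the replicated groups.

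How closely induced cells resembled OPCs was asked by comparing them with the single library of OPCs from epiblast stem cells and therefore of another cell source. Strain and culture differed too. Gpm6a, a neuronal and glial membrane protein, was at 123 FPKM in OPCs and at 0, 0.029 and 0 in the induced libraries. Fabp7, a fatty acid carrier of neural progenitors, was at 21.9 ± 5.3 against 1724 (fell by 6.26, SE 0.36, limma adjusted p = 7.0e-05), and Ckb, brain creatine kinase, was at 15.5 ± 4.55 against 1085. Among the largest rises were S100a6, a calcium-binding protein, at 764 ± 162 against 0.283 FPKM, and Spp1, osteopontin, at 926 ± 311 against 1.95. So were Igfbp7 at 228 ± 12.8 against 0.208, Serpina3n, and the surface antigen gene Ly6a, listed at 0 in OPCs and at 426, 164 and 221 in the induced libraries. Nnat, an imprinted membrane protein gene, was at 1.82 ± 0.797 against 150.1. Rps18 of the small ribosomal subunit was at 76.7 FPKM in OPCs and at 0.344, 0 and 0.195 in the induced libraries. The ribosomal protein genes Rps2 and Rpl21 were at 40.2 and 11.9 FPKM in OPCs and below 1 FPKM in every other library. Technical differences of the OPC library cannot be told apart from differences of the cells, because it is a single library. An FPKM near 0 in such a file can be a failed estimate, and 17 of 82 ribosomal protein genes were below 1 FPKM in all 8 libraries.

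By list, 18 of 28 OPC genes were lower than in the OPC library and 8 higher (18 and 8 adjusted over the list alone; camera adjusted p = 0.00201, adjusted p = 0.365 with an estimated correlation). Olig1, a partner of Olig2, was at 6.42 ± 2.39 FPKM against 308, and Ncan, a brain proteoglycan, at 0.772 ± 0.478 against 48.7. Of the lineage factors Sox10, Nkx6-2 and Zfp536 were higher by 3.04, 4.26 and 2.91, and Olig2 was lower, at 47.1 ± 14 against 127 FPKM, a call lost without induced replicate 3 (3 and 1 adjusted over the list alone; camera adjusted p = 0.103). Myelin genes went the other way from precursor genes, with 15 of 24 higher and 4 lower (16 and 4 adjusted over the list alone; camera adjusted p = 0.00454, adjusted p = 0.387 with an estimated correlation). Mag was at 25.7 ± 10.6 against 0.0331 FPKM, while Bcas1, Gpr37, Car2 and Plekhh1 were at 1.95 ± 1.73, 0.302 ± 0.183, 0.426 ± 0.168 and 0.559 ± 0.246 against 9.45, 2.33, 7.51 and 1.59. The call of Bcas1 was lost after median-ratio scaling and without induced replicate 3 or either uninduced replicate. Of 18 Schwann cell genes 11 were higher and Pou3f1, Sox2 and Fabp7 lower (11 and 3 adjusted over the list alone; camera adjusted p = 0.038, adjusted p = 0.443 with an estimated correlation). That list call was lost after median-ratio scaling (camera adjusted p = 0.0858) and without induced replicate 2 (0.0617). Pou3f1, a factor of myelinating glia, was at 1.02 ± 0.23 against 17.8 and Sox2 was at 7.32 ± 3.58 against 60.9.

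All 32 fibroblast genes tested were higher in induced cells than in OPCs as deposited, and 31 after median-ratio scaling (32 adjusted over the list alone; camera adjusted p = 1.7e-13, adjusted p = 0.210 with an estimated correlation). Fn1 was at 285 ± 32.6 against 0.808 FPKM, and Postn was listed at 0 in OPCs and at 159, 174 and 172 in the induced libraries. All 28 cell cycle genes were lower (28 adjusted over the list alone; camera adjusted p = 1.7e-13, adjusted p = 0.365 with an estimated correlation), with Mki67 at 8.35 ± 1.58 against 62.4 and Mcm5, a helicase subunit of DNA replication, at 5.66 ± 1.14 against 50.6. Of 22 cholesterol synthesis genes 19 were lower (19 adjusted over the list alone; camera adjusted p = 5.5e-08, adjusted p = 0.365 with an estimated correlation), with Sqle, an early enzyme of sterol synthesis, at 17.3 ± 0.613 against 107. Of 16 astrocyte genes 12 were lower, with Slc1a3, a glutamate transporter, at 1.2 ± 0.108 against 94.9 and Mlc1 at 0, 0.0384 and 0.0487 against 46.5 FPKM. Gja1 and S100b were higher by 1.28 and 3.17, and so was Gfap, listed at 0 in OPCs and at 0.693, 0.83 and 1.01 FPKM in the induced libraries (12 and 3 adjusted over the list alone; camera adjusted p = 4.8e-04, adjusted p = 0.210 with an estimated correlation). Of 12 neural progenitor genes 10 were lower and Hes1, a target of Notch, was higher by 2.48 (10 and 1 adjusted over the list alone; camera adjusted p = 1.6e-04, adjusted p = 0.210 with an estimated correlation). Of 22 interferon response genes 16 were higher (19 adjusted over the list alone; camera adjusted p = 4.8e-04, adjusted p = 0.50 with an estimated correlation), with Bst2, which tethers virions, at 33 ± 8.41 against 0.82. Of 29 Hox genes 20 were higher, with Hoxa10 at 10.1 ± 1.25 against 0.55. Hoxa2, Hoxa3, Hoxb2 and Hoxb3, which are expressed up to the hindbrain, were lower with changes of -2.59, -0.98, -0.86 and -1.03 (21 and 4 adjusted over the list alone; camera adjusted p = 0.00912, adjusted p = 0.365 with an estimated correlation). Camera called 8 further lists. Higher were 14 of 15 TGF-beta and YAP targets (15 adjusted over the list alone; camera adjusted p = 1.0e-06), 11 of 13 immediate early genes (11 adjusted over the list alone; camera adjusted p = 0.00119), 9 of 11 contractile genes (10 adjusted over the list alone; camera adjusted p = 6.1e-04) and 10 of 16 p53 and senescence genes (10 adjusted over the list alone; camera adjusted p = 0.00164). With an estimated correlation these 4 had adjusted p = 0.261, 0.210, 0.365 and 0.50. Of 13 neuron genes 8 were lower (8 adjusted over the list alone; camera adjusted p = 0.00454, adjusted p = 0.240 with an estimated correlation). The macrophage list was called upward with a median change of 2.33 (camera adjusted p = 0.0132, adjusted p = 0.587 with an estimated correlation) and lost its call after median-ratio scaling (camera adjusted p = 0.051). Of 10 cartilage and bone genes 7 were higher (7 adjusted over the list alone; camera adjusted p = 0.0396, adjusted p = 0.365 with an estimated correlation). That call was lost after median-ratio scaling (camera adjusted p = 0.0789) and without induced replicate 2 (0.0525) or either uninduced replicate (0.0524 and 0.0528). The adipocyte list, called upward with a median change of 0.85 (camera adjusted p = 0.0492, adjusted p = 0.50 with an estimated correlation), lost its call after median-ratio scaling (0.128) and without induced replicate 2 (0.0525) or 3 (0.0579). Zfp536, Olig2 and the minority members named in these lists, apart from Fabp7, were chosen after their values were seen.

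limma called 6538 genes, 3572 higher and 2966 lower than in OPCs, 54.6% higher as deposited and 44.3% after quantile normalization. Of the 40 genes named in this comparison, 38 kept their call in each omission of a library.

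Whether the MBP transgene changed the induced cells was asked by comparing the 3 induced libraries with the single induced library without it. Pmel was at 100.4 ± 3.94 FPKM with and 121 without the transgene, and Sox2 at 7.32 ± 3.58 and 10.7. Bcan, a brain proteoglycan of OPCs, was at 7.7 ± 5.03 and 10.2, and Ngfr, a neurotrophin receptor of Schwann cells, at 5.12 ± 1.59 and 7.91. None of these 4 passed (limma adjusted p = 0.533 to 0.634). Isg15 and Bst2 of the interferon list had higher values with the transgene, Isg15 at 19.2, 10.1 and 13.3 FPKM against 2.6 and Bst2 at 40.2, 23.8 and 35.1 against 8.69. They did not pass either (limma adjusted p = 0.533 for both).

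limma called 3 of 12642 genes at the threshold, against 806 at an unadjusted p under 0.05. A share of 0.05 of the tested genes would fall there without any effect. The median change of all genes, 0.24 as deposited and -0.001 after median-ratio scaling, can add to it. The 806 were therefore not read as effects of the transgene. Arhgap21, a regulator of small GTPases, was listed at 0 without the transgene and at 7.98, 7.36 and 7.01 FPKM with it (adjusted p = 0.00379). It was also listed at 0 in fibroblasts and in both uninduced libraries and was at 15.1 in OPCs. Gphn, gephyrin, was listed at 0 without and at 5.53, 5.3 and 4.85 with it (adjusted p = 0.00789), and Snora28, a small nucleolar RNA chosen after its values were seen, was at 28.3 without and listed at 0 in the other 7 libraries (adjusted p = 6.6e-05). These zeros were not read as absence, since 13 genes were listed at 0 in 1 replicate of a group and at 10 FPKM or more in another. No member of any of the 25 lists passed, also 0 adjusted over the list alone. Camera called 10 lists relative to a median change of all genes of 0.24, 6 of which were also called after median-ratio scaling. Besides the OPC and interferon lists these 10 were the fibroblast list, upward, and the myelin, Schwann, melanocyte, neuron, neural progenitor, endothelial and adipocyte lists, downward. After that scaling the calls of the neuron, neural progenitor, endothelial and adipocyte lists were lost. Newly called upward by it were the contractile smooth muscle, p53 and senescence, TGF-beta and YAP, immediate early and macrophage lists. Those of the myelin (camera adjusted p = 0.821) and neural progenitor lists (0.158) were lost without induced replicate 1, those of the fibroblast (0.0983) and endothelial lists (0.105) without induced replicate 2, and the latter also without uninduced replicate 2 (0.161). The OPC list had a median change of -0.04 (camera adjusted p = 1.3e-10, adjusted p = 0.395 with an estimated correlation) and the interferon list 0.79 (camera adjusted p = 0.00181, adjusted p = 0.696 with an estimated correlation). The macrophage list had a median change of 0.85 and was not called (camera adjusted p = 0.875, adjusted p = 0.982 with an estimated correlation). At the preset correlation it was called upward after median-ratio scaling (camera adjusted p = 0.029) and without induced replicate 1. Its members varied together, with an estimated correlation of 0.94 against the preset 0.01. These 2 calls therefore count its genes as nearly independent, which they were not, and no conclusion is drawn from them. The lowest of the 25 was adjusted p = 0.338 with an estimated correlation. The count was 7 without induced replicate 1 and 6 without induced replicate 2, and Gphn lost its call without induced replicate 3 or either uninduced replicate, so a lone library leaves small effects of the transgene open.

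What infection and culture without induction changed was asked by comparing the 2 uninduced libraries with the fibroblast library. The same uninduced libraries also stand in the comparison with induced cells. The 5 largest rises were those of Lcn2, Mmp3, Saa3, S100a8 and Tslp. Lcn2 and Saa3, proteins of the acute phase, were at 125 ± 24.5 and 88.6 ± 20.6 FPKM, with Lcn2 listed at 0 and Saa3 at 0.333 in fibroblasts. Mmp3, a matrix protease, was at 159 ± 48.7 against 3.29 (a rise of 5.19, SE 0.34, limma adjusted p = 0.00191), Tslp, a cytokine, at 74.4 ± 34.3 against 1.03, and S100a8, a calcium-binding protein of myeloid cells, at 52 and 28.4 and listed at 0 in fibroblasts. The 5 largest falls were those of Cthrc1, from 108 to 0.597 ± 0.213 FPKM, Mfap4 from 44.5 to 0.448 ± 0.209, Col12a1, a fibril-associated collagen, from 202 to 10.2 ± 1.1, C1qtnf3, and Slc38a4, an amino acid transporter.

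By list, 24 of 28 cell cycle genes were lower (25 adjusted over the list alone; camera adjusted p = 4.4e-14, adjusted p = 0.445 with an estimated correlation), with Mki67 at 2.61 ± 0.0682 against 13.8 FPKM and Top2a at 5.31 ± 0.357 against 27.7. Of 32 fibroblast genes 16 were lower, including Col1a1 at 55.3 ± 1.39 against 523 and Lum at 12.4 ± 3.23 against 108. Cd44, a hyaluronan receptor, and Dpt were higher by 1.62 and 1.18 (19 and 3 adjusted over the list alone; camera adjusted p = 2.2e-04, adjusted p = 0.427 with an estimated correlation). Of 11 contractile genes 7 were lower, led by Actg2 at 2.08 ± 0.536 against 26.6, and Rgs5, a pericyte marker, was higher (8 and 1 adjusted over the list alone; camera adjusted p = 1.6e-04, adjusted p = 0.468 with an estimated correlation). Of 8 adipocyte genes 5 were higher (8 adjusted over the list alone; camera adjusted p = 1.4e-07, adjusted p = 0.427 with an estimated correlation). Among these were Fabp4, at 72.7 ± 34 against 4.78 FPKM, the fat hormone gene Adipoq, listed at 0 in fibroblasts and at 3.56 and 10.8 in the uninduced libraries, and Cd36, a fatty acid transporter. Pparg and Cebpa, regulators of fat cell formation, were at 6.38 ± 1.94 against 1.39 and 7.02 ± 0.795 against 2.91. Of 22 interferon response genes the proteasome subunit genes Psmb8 and Psmb9 were higher by 2.19 and 2.29 (9 adjusted over the list alone; camera adjusted p = 3.5e-09, adjusted p = 0.468 with an estimated correlation). The macrophage list was called upward with no member past the threshold (median change 0.77; 0 adjusted over the list alone; camera adjusted p = 0.0219, adjusted p = 0.652 with an estimated correlation). That call was lost after median-ratio scaling (camera adjusted p = 0.204) and without uninduced replicate 2 (0.293). Of 16 p53 and senescence genes Perp and Cdkn2a, a cell cycle inhibitor of senescent cells, were higher by 3.74 and 2.38 (5 adjusted over the list alone, 9 higher after median-ratio scaling; camera adjusted p = 2.7e-04, adjusted p = 0.505 with an estimated correlation). Among the lineage factors Sox10 was listed at 0 in fibroblasts and at 1.9 and 3.31 FPKM without doxycycline. Nkx6-2, at 3.92 ± 2.45 against 0.0941, had limma adjusted p = 0.0517 and passed after median-ratio scaling (2 adjusted over the list alone; camera adjusted p = 0.0069, adjusted p = 0.427 with an estimated correlation, 0.0637 after median-ratio scaling). Of 28 OPC genes Cspg4, the NG2 proteoglycan, Pcdh15 and Megf11 were higher by 0.84, 0.59 and 0.76 (3 adjusted over the list alone; camera adjusted p = 0.0393, adjusted p = 0.505 with an estimated correlation). The OPC list lost its call after median-ratio scaling (camera adjusted p = 0.282) and without uninduced replicate 2 (0.246). So did the myelin list, called upward with a median change of 0.07 (camera adjusted p = 0.0399, adjusted p = 0.505 with an estimated correlation), with 0.244 and 0.238. Called downward were cholesterol synthesis genes (14 lower adjusted over the list alone, 7 after median-ratio scaling; camera adjusted p = 2.0e-05, adjusted p = 0.468 with an estimated correlation) and TGF-beta and YAP targets (8 lower adjusted over the list alone, 7 after median-ratio scaling; camera adjusted p = 0.010, adjusted p = 0.468 with an estimated correlation). Skeletal muscle, immediate early and cartilage and bone genes were called downward as well (camera adjusted p = 0.00394, 0.0295 and 0.0399), each with adjusted p = 0.427 with an estimated correlation. The call of the immediate early list was lost after median-ratio scaling (camera adjusted p = 0.0637), and without uninduced replicate 1 that list and the cartilage and bone list lost theirs (0.147 for both). Cd44, Dpt, Pparg, Cebpa, Cd36 and Pcdh15 were chosen after their values were seen.

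limma called 1295 genes, 483 higher and 812 lower, 37.3% higher as deposited and 50.6% after median-ratio scaling, which called 2218. The share was 44.1% after quantile normalization, which called 2024, and 49.3% without small RNA genes, which called 2138. The count was 748 with no filter on low genes, 491 without uninduced replicate 2, 514 without induced replicate 3 and 595 without uninduced replicate 1. Of the 31 named genes that passed, 15 lost their call in at least 1 omission, among them S100a8, Lum, Cd44, Dpt, Adipoq, Pparg, Cebpa, Psmb8, Psmb9, Perp and all 3 OPC genes.

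The place of each library between fibroblast and OPC was described without a test, because both ends are single libraries. Over 196 genes at least 8-fold higher in OPCs than in fibroblasts, the median position, with 0 at the fibroblast and 1 at the OPC value, was 0.149 ± 0.0253 in induced cells with MBP, 0.136 without MBP, and 0.0126 and 0.0358 in the uninduced replicates. Over 411 genes at least 8-fold higher in fibroblasts it was 0.228 ± 0.0401 with MBP, 0.364 without, and 0.118 and 0.136 in the uninduced replicates. With a pseudocount of 0.1 in place of 1, induced cells with MBP were at 0.248 over 667 OPC-high genes and at 0.147 over 1142 fibroblast-high genes, so which set lay farther toward OPCs depended on the pseudocount. Of the OPC-high genes 23.3% ± 2.06 lay past the midpoint in induced cells, and of the fibroblast-high genes 22.5% ± 4.14. Among the 843 genes that rose at least 2-fold on induction, 63 were OPC-high, against 13.1 expected from independent lists, and 24 were fibroblast-high, against 27.4. Among the 384 that fell at least 2-fold, 107 were fibroblast-high, against 12.5 expected, and 3 were OPC-high, against 5.95. Of the 843 that rose, 236 (28.0%) were below 1 FPKM in OPCs, including Pmel. Across genes, which are not independent replicates, the change on induction correlated with the difference between OPCs and fibroblasts at r = 0.344 and a Spearman rank correlation of 0.317. These comparisons share no library but start from similar cells, since the uninduced libraries correlated with the fibroblast library at 0.906 and 0.898. OPC-high genes were near the fibroblast level before induction and could hardly fall. The overlaps and this correlation are therefore partly built in and are no independent evidence of a move toward OPCs.

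**Figure D3:**
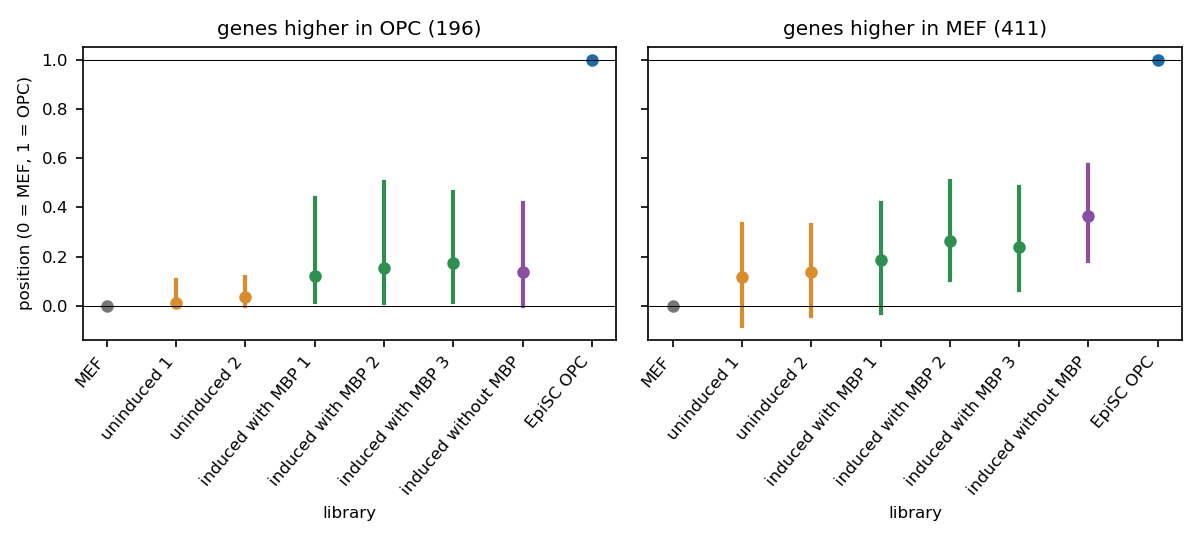
Median position of each library between the fibroblast value (0) and the OPC value (1) on the log2(FPKM + 1) scale, for 196 genes at least 8-fold higher in OPCs and 411 at least 8-fold higher in fibroblasts, with lines from the 25th to the 75th percentile over genes. The induced libraries with MBP average 0.149 and 0.228 (0.248 and 0.147 with a pseudocount of 0.1), and the uninduced libraries lie at 0.0126 to 0.136.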

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

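Of 3118 values of the 205 named gene results under other settings, 2796 stayed on their side of the threshold, 316 fell short of it and 6 came past it. Among results that passed in the main or the other setting, 0 changed direction. A change of direction of a result that passed in neither setting was not counted. The count of genes changed between induced and uninduced cells was 3651 with a pseudocount of 0.1, 2957 with no filter, 3585 without a variance trend, 4075 with median-of-ratios scaling and 3840 with quantile normalization, against 3605. A minimum of 2-fold left 1227 genes in that comparison, 1445 against fibroblasts and 3935 against OPCs, since it drops smaller changes by construction. Uninduced cells against fibroblasts gave 748 genes with no filter, 2218 with median-of-ratios scaling, 2024 with quantile normalization and 2138 without small RNA genes, against 1295. Induced cells with against without MBP gave 6 genes with a pseudocount of 0.1 and 11 with no filter, against 3. The cause was not tested in these cases. Camera's 68 list calls became 0 with an estimated correlation, and 54 of them were kept after median-of-ratios scaling. The position of induced cells over OPC-high genes was 0.248 with a pseudocount of 0.1 and 0.117 over genes 4-fold apart, against 0.149, and over fibroblast-high genes it was 0.147 with that pseudocount, against 0.228, and the cause was not tested.

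Leaving out single replicates, where a lone remaining library is assumed to vary like the other groups, gave 1400 to 3545 genes for induced against uninduced cells, 1331 to 2528 against fibroblasts, 5111 to 6700 against OPCs, 2 to 7 for the MBP transgene and 491 to 1656 for uninduced cells against fibroblasts. It gave 64 to 72 list calls and positions of 0.137 to 0.163 and 0.211 to 0.250. With fewer libraries the spread rests on fewer degrees of freedom. With the replicate number as a block the count for induced against uninduced cells was 4217 (3131 higher, 1086 lower). Snap25, Dhcr7, Hoxa6, Hoxb3 and Hoxc10 then lost their calls. Induced replicate 3 shares its number with no uninduced library, so under the block it added nothing to the changes. Those of Snap25, Dhcr7 and Hoxa6 were -0.55, 0.54 and 0.47, the same as without that library. Leaving it out without a block gave 1601 genes. The blocked count is therefore no check on all induced libraries. The titles of induced and uninduced libraries carry the same Rd number with and without doxycycline, but do not say what it marks. The samples were not treated as paired in the main test, because the labels do not say that the number marks a batch and only 2 pairs share one. The deviations of same-numbered libraries correlated at 0.285 and 0.214, and those of uninduced replicate 2 and induced replicate 3, of unlike number, at 0.162. The first 2 values are not separate checks, because the deviations of 2 uninduced libraries mirror each other. A shared batch is left open. Pooling all 4 induced libraries, an alternative chosen after seeing the data, gave 3569 genes. Depth could not be examined, because FPKM carries no read number.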

Other observations

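All tests in this part were chosen after the result was seen.

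Libraries of the same group differed in immune cell genes. Macrophage markers were far lower in induced replicate 1 than in the other 2 induced replicates. Lyz2, the lysozyme of myeloid cells, was at 9.59 FPKM against 116 and 121, C1qa, a complement component, at 1.41 against 22.1 and 23.7, and Emr1, the F4/80 antigen of macrophages, at 1.27 against 12.5 and 15.1. The uninduced replicates had Lyz2 at 39.0 and 44.2 FPKM, but their macrophage list medians were 2.68 FPKM in replicate 1 and 6.28 in replicate 2. The list median was thus lower in replicate 1 of both groups, and it was 1.69 in the induced library without MBP. All 16 tested markers were lower in induced replicate 1 than in both other induced replicates. This is the pattern itself, so a different share of macrophages was left open. A difference in scaling is argued against as the whole cause, since the median log2 difference of replicate 1 from the other replicates was -2.23 as deposited and -2.27 after median-of-ratios scaling. Other library effects, such as RNA quality, were not tested. The design names no difference between these replicates, and no biological explanation was tested.

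Schwann cell genes and some pigment genes rose together with oligodendrocyte genes on induction. Dct was listed at 0 in the OPC library, a zero that is not read as absence and does not stand for the other pigment genes. Pigment cells that make Tyr, Tyrp1, Mlana, Slc45a2 and Trpm1 in amount would bring these transcripts. The highest of their means over the 3 induced libraries was 0.437% of that of Pmel, which argues against such cells as the source. Cells of the pigment lineage without these transcripts were left open. Schwann cells kept at an unchanged share would show in the uninduced libraries. There the median over all 18 tested Schwann list members was 2.34% and 14.5% of the induced level in the 2 replicates. This ratio restates the rise itself, so it is no separate test and no conclusion about Schwann cells is drawn from it. Library scaling does not account for the rise, because 13 of 18 members still rose after median-of-ratios scaling and after quantile normalization. An action of the induced factors, Sox10 among the candidates, on genes shared by glia and pigment cells, or growth under induction of rare Schwann cells left after the fibroblasts were depleted with beads against A2B5, may explain the pattern and was not tested.

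The 3 genes called between induced cells with and without the MBP transgene, Arhgap21, Gphn and Snora28, were each listed at 0 on one side (3 of 3). Failed estimates and an effect of the transgene or of the single sample cannot be told apart here, because the file holds no read counts and the group without MBP has 1 library.

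Lars2 was at 6790 FPKM in induced replicate 1 and listed at 0 in the other 7 libraries. Snora5c was at 5896 FPKM in induced replicate 2 and listed at 0 in the other 7. Filip1l was at 30.6, 0 and 28.0 FPKM in induced replicates 1, 2 and 3. Of 13 genes listed at 0 in 1 replicate and at 10 FPKM or more in another of its group, 10 were small RNA genes.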
